A study of Mus musculus with 8 samples.

How the data were processed

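Chromatin from undifferentiated F9 cells, a mouse embryonal carcinoma line, was crosslinked with formaldehyde, sonicated and immunoprecipitated (IP) with an antibody against Ezh1 or against Ezh2, per the labels' protocols. IP DNA and input DNA were both amplified by ligation-mediated PCR; input was labelled with Cy3 and IP DNA with Cy5 on all 8 arrays, so dyes were not swapped. There were 2 replicates for each of the 2 antibodies, and each replicate took 2 arrays, one of each of 2 array designs that tile different promoters, so that 8 arrays were used. The labels describe a check of both antibodies by the submitters in cells with inducible Gal4 fusions of each protein; that check was not analysed here. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. They also do not say whether IPs shared an input.

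Probe intensities were extracted with Agilent Feature Extraction 9.5.1.1, per the file headers. The processed intensity of each channel was background-subtracted, spatially detrended and dye-normalized within the array by a linear factor, with low values replaced by a surrogate, per the file headers. The deposited log10 ratios of Cy5 over Cy3 were equal in the series table and in the scanner files (largest gap 0), which settles their scale, centring and direction. The medians of these deposited log10 columns were -0.019, -0.018, -0.043 and -0.034 on design 1 and 0, -0.017, -0.040 and -0.031 on design 2, for Ezh1 replicates 1 and 2 and Ezh2 replicates 1 and 2 in turn. The genome build of the probe positions is not given in the sources used here, so coordinates are those of the files.

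The file headers name an Agilent scanner for replicate 1 of both antibodies and a GenePix scanner for replicate 2 of both, so the replicate number is also the scan batch. Each batch holds both antibodies. Median input signal was 2.58 to 3.22 times the local background on the Agilent scans and 9.97 to 15.7 times on the GenePix scans. Between 87.9% and 99.5% of probes had input well above background. The number of arrays limits the precision.

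The main values were log2 of the processed Cy5 over the processed Cy3 signal, centred on the median of each array's non-control probes, without loess or quantile steps. Control spots and probes with an outlier flag on an array were left out of that array. A promoter's value was the mean over the probes that the files annotate to that gene, with at least 3 probes; probes of a divergent promoter counted for both genes, and 2977 promoters held such probes. Of 17095 gene names in the files, 187 had too few probes, which left 16908 promoters with a median of 28 probes. Current symbols were found for 16119 of these names through the accession in the files and the reference gene tables, and the name in the files was kept otherwise.

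limma's lmFit was run on the 4 IP replicates with 1 coefficient per antibody, which left 2 residual degrees of freedom and 6.77 prior degrees of freedom. A promoter was called enriched when treat, with a log2 threshold of 0.5, gave a Benjamini-Hochberg adjusted p under 0.05 above the array median. Promoters that differed between the antibodies were called with eBayes on Ezh2 minus Ezh1 at the same adjusted threshold. An exact permutation test of 2 against 2 samples cannot give a two-sided p below 0.333, so none was used for single promoters. Overlaps of calls were tested with Fisher's exact test, one-sided, over all promoters tested. Groups chosen later are given as counts only.

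The choices of test, alternatives, gene lists and named genes were made before the data were examined, except where stated otherwise. There were 21 lists. The transcription factor lists were Hox clusters, homeodomain and other developmental transcription factors, the Sox, Fox, Gata and Tbx factors, and basic helix-loop-helix lineage factors. The signalling lists were Wnt ligands, Fgf ligands, and the Bmp, Gdf and hedgehog ligands. Lists tied to the cell line and the proteins were pluripotency factors, primitive and parietal endoderm markers, PRC2 and PRC1 subunits, and cell cycle inhibitors. Lists of widely expressed genes were cell cycle and replication, ribosomal proteins, housekeeping metabolism and proteasome subunits. Lists of genes of other tissues or of particular regulation were olfactory and vomeronasal receptors, lymphoid and myeloid markers, neuronal receptors and channels, imprinted genes, keratins, and spermatogenesis and germ line. Members were matched by current symbol or by the file's name. Each list was tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 21 lists. The preset treats a list's promoters as nearly independent, so its p-values are too small where members vary together. With an estimated correlation camera rests on the 2 residual degrees of freedom and had little power. A call lost there does not show that a list lacks signal. camera compares a list with all other promoters, whereas fry tests whether the list's own members move one way on balance.

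Genes named were the 10 with the highest log2 ratio among those enriched for each antibody with both replicates above 0.5, and the 10 with the largest difference in each direction among those called, with both replicates of one antibody above both of the other. For each list they were the 2 members with the highest and the 1 with the lowest mean over all replicates. A fixed set was added where measured, among them Ezh1, Ezh2, Eed, Suz12, Pou5f1, Nanog, Sox2, Gata4, Gata6, Sox17, Foxa2, Pax6, Cdkn2a, Hoxd10, Actb and Gapdh. Ezh1 and Nanog had no promoter in the set tested. Not every gene that meets these rules is named in the text. Other genes named where a count was 5 or fewer, or in the closing observations, were chosen after their values were seen.

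The fitting steps were tested on simulated data in which 200 promoters were shifted. Values were independent normal draws around 0, with spreads drawn from limma's prior. They held no probe bias, scan batch effect or correlation between promoters, so the rates apply to that simpler case. For Ezh2, log2 ratios of 1.0, 1.5 and 2.0 were recovered as enriched in 82%, 100% and 100% of promoters. For Ezh1, ratios of 0.5, 0.75 and 1.0 were recovered in 0%, 0% and 83.5%, and a ratio of 1.0 without any Ezh2 in 76%. Differences of 0.5, 0.75 and 1.0 between the antibodies were recovered in 0%, 80.5% and 95% of promoters, with 0, 13 and 7 false calls, and a difference of 1.0 toward Ezh1 in 95.5%, with 8 false calls. No promoter was falsely called enriched, which was nearly fixed in advance since unshifted promoters were centred on 0, below the threshold of 0.5.

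Alternatives covered background correction (normexp with an offset of 50), loess within arrays, centring on the mode, MAD scaling, quantile normalization, the filter on dim probes, flagged probes, the median over probes, probes within 1 kb of the start, the highest window of 5 probes, a minimum of 8 probes, the deposited log10 ratios, each array design alone, limma's trend and robust options, the replicate number as a block, treat thresholds of 0 and 1, and leaving out each replicate. Scaling of each array to one 99th percentile, removal of a probe length trend and a crossed block were added after seeing the data. A correction for probe GC content was not run, since no probe sequence or genome was at hand. Analyses used R 4.3.3, data.table (version 1.17.8) and limma 3.58.1; files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.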

Results

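Ezh1 and Ezh2 are the alternative catalytic subunits of PRC2, the Polycomb complex that methylates histone H3. Their binding to promoters was compared in undifferentiated F9 cells, which can be induced to form primitive and parietal endoderm. Each antibody had 2 replicates, and each replicate was read over 237195 probes of array design 1 and 237185 probes of array design 2. Values are log2 ratios of IP over input, averaged over the probes of a promoter and centred on each array's median, so they measure signal relative to the array's typical probe. Ratios are given as mean ± SD (n = 2), and differences between antibodies as mean ± SE from limma. All tiled intervals are in the coordinates of the files, whose genome build is not given in the sources used here. Replicate 1 and replicate 2 are also 2 scan batches, each with both antibodies.

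The first comparison asked which promoters carried Ezh2. The highest Ezh2 signal lay at Msx1, a homeobox gene of craniofacial development (chromosome 5, 36903331 to 36911059), with a log2 ratio of 3.39 ± 0.41 (SD, n = 2). That is 10.5 times the array's median ratio of IP over input. Close behind were the eye and forebrain regulator Six3 at 3.38 ± 0.56 with its antisense partner Six3os1 at 3.21 ± 0.40, the oligodendrocyte and motor neuron factor Olig2 at 3.31 ± 0.49, and the paired-box genes Pax3 at 3.30 ± 0.39 and Pax9 at 3.27 ± 0.53. The LIM-homeobox gene Lhx9 reached 3.22 ± 0.34, Nkx2-3 3.27 ± 0.47 and the Hox-cluster microRNA mmu-mir-196b 3.35 ± 0.49 over 5 probes. The tiled intervals of Six3 and Six3os1 overlap, so their values are not independent. Ezh2 was enriched at 1448 of 16908 promoters, or 8.56%, and at 1481 with the scan batch as a block. All 1448 had a ratio above 0.5 in both replicates, which the call itself nearly ensures.

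Most promoters of 4 lists of transcription factors that set body plan and lineage passed. Of 33 Hox promoters, 32 passed for Ezh2 (33 when adjusted over the list alone), among them Hoxa9 at 3.16 ± 0.47, Hoxd10 at 3.10 ± 0.26 (chromosome 2, 74527937 to 74538715), Hoxb3 at 3.09 ± 0.40 and Hoxb6 at 3.08 ± 0.47. Among homeodomain and other developmental transcription factors, 71 of 76 passed (72 over the list alone), while Pax4 was at 0.24 ± 0.15; the eye regulator Pax6 stood at 2.84 ± 0.50. Of the Sox, Fox, Gata and Tbx factors 37 of 53 passed (37 over the list alone), such as Gata6 at 3.15 ± 0.53 (chromosome 18, 11253676 to 11261692) and Foxb1 at 3.09 ± 0.44, with the somite gene Tbx6 lowest at -0.24 ± 0.24. Gata2, a haematopoietic regulator, was at 3.17 ± 0.56. Of basic helix-loop-helix lineage factors 17 of 23 passed (17 over the list alone), including the proneural gene Neurog2 at 3.10 ± 0.36, whereas the muscle gene Myog was at -0.12 ± 0.13. Adjusted p values of limma's camera for these 4 lists were 1.66e-28, 1.31e-44, 1.80e-23 and 3.85e-13 in the order given. They assume a correlation of 0.01 between members, whereas the estimates, themselves imprecise with so few replicates, were 0.94, 0.88, 0.59 and 0.49. Such p-values therefore overstate the evidence, here and for the other lists whose members vary together. All 4 were lost with an estimated correlation (adjusted p = 0.327 for each), a setting with little power in which no list passed.

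Signalling ligands, endoderm genes, neuronal genes and imprinted genes were enriched in part. For Wnt ligands 17 of 19 passed (17 over the list alone), with Wnt11 at 2.62 ± 0.40 and Wnt7b at 2.40 ± 0.49 highest and Wnt5b lowest at -0.035 ± 0.031. For Fgf ligands 10 of 21 passed (11 over the list alone), with Fgf16 at 2.62 ± 0.50 and Fgf9 at 2.31 ± 0.34, while Fgf1 was at -0.32 ± 0.017. For the Bmp, Gdf and hedgehog ligands 11 of 28 passed (11 over the list alone), with Ihh at 2.17 ± 0.32 and Bmp2 at 1.90 ± 0.25, while the left-right gene Lefty2 was at -0.53 ± 0.062. Among primitive and parietal endoderm markers, the genes F9 cells switch on upon differentiation, 11 of 24 passed (12 over the list alone). They included Pdgfra at 2.79 ± 0.35, Gata4 at 2.76 ± 0.44, Foxa2 at 2.52 ± 0.16 and Sox17 at 2.13 ± 0.068, with Gata4, Gata6, Foxa2 and Sox17 also in the transcription factor list; the collagen chaperone gene Serpinh1 was at -0.29 ± 0.16. For neuronal receptors and channels 18 of 37 passed (21 over the list alone), with the potassium channel gene Kcna1 at 2.37 ± 0.43 and the glutamate receptor gene Grin2c at 2.00 ± 0.39, while Gria1 was at -0.15 ± 0.038. For imprinted genes 11 of 20 passed (12 over the list alone), with the growth factor gene Igf2 at 2.49 ± 0.29 and Grb10 at 2.40 ± 0.20, while Peg3 was at -0.54 ± 0.015. In the order given, camera's adjusted p was 1.65e-12, 1.11e-05, 0.00455, 1.11e-05, 4.26e-15 and 1.18e-06. Those calls were lost with an estimated correlation, where the adjusted p = 0.327, 0.401, 0.524, 0.380, 0.327 and 0.327. With the batch as a block, adjusted p for these 6 lists and the 4 transcription factor lists reached at most 8.55e-05, while on array design 2 alone the Bmp, Gdf and hedgehog list had 0.0722.

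The lists of Polycomb genes, cell cycle inhibitors and pluripotency factors did not pass. Their enriched shares, 16%, 30% and 9.09%, were nonetheless above the 8.56% of all promoters. Of 25 PRC2 and PRC1 subunits 4 passed (5 over the list alone), among them the chromobox genes Cbx8 at 2.87 ± 0.51 and Cbx2 at 0.93 ± 0.15, and Bmi1 at 2.62 ± 0.24. Promoters of the PRC2 core stood near the array median, with Ezh2 at 0.12 ± 0.15 (-0.076 with normexp), Eed at 0.012 ± 0.041 (-0.090 with normexp and -0.061 with loess) and Suz12 at -0.039 ± 0.083 (0.10 with centring on the mode), and Phc1 was lowest at -0.44 ± 0.12. The PRC list had an adjusted p of 0.664, with a median of -0.039 below and a mean of 0.36 above the array median; without Ezh2 replicate 2 its adjusted p was 0.0382. Of 10 cell cycle inhibitors 3 passed (4 over the list alone), namely Cdkn1c at 2.49 ± 0.39, Cdkn2a at 2.06 ± 0.15 and Cdkn2c at 1.35 ± 0.048, while Trp53 was at -0.45 ± 0.048. That list had an adjusted p of 0.0718, which became 0.00419 with the batch as a block, 0.00865 without Ezh2 replicate 1 and 0.00321 without Ezh2 replicate 2. Of 22 pluripotency factors 2 passed (2 over the list alone), the epiblast factor Otx2 at 2.66 ± 0.29 and Dppa3 at 1.43 ± 0.28. Pou5f1, the central pluripotency factor (chromosome 17, 33601969 to 33609544), was lowest at -0.43 ± 0.053, and Sox2 was at -0.095 ± 0.088 (0.036 with centring on the mode). The pluripotency list had an adjusted p of 0.191 downward, with a median of -0.12 and a mean of 0.10, and it stood 0.040 above other promoters with normexp.

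Lists of widely expressed genes had medians below the array median, though some members lay slightly above it. No promoter passed among 28 of cell cycle and replication, 76 of ribosomal proteins, 25 of housekeeping metabolism and 30 of proteasome subunits, over all genes or over the list alone. Their list medians were -0.22, -0.29, -0.24 and -0.20. All 4 lists were below other promoters by camera, with adjusted p of 1.11e-05, 2.79e-14, 8.04e-05 and 1.92e-05. An estimated correlation ended these calls (adjusted p = 0.327, 0.327, 0.340 and 0.327), whereas the batch as a block did not (0.00293, 2.63e-07, 0.00473 and 0.00419). Examples were Bub1 at 0.074 ± 0.038, Ccne2 at 0.0075 ± 0.21 and Aurka at -0.42 ± 0.055 for the cell cycle, and Rpl30 at -0.04 ± 0.12, Rps29 at -0.086 ± 0.024 and Rpl36 at -0.59 ± 0.11 for ribosomes. The metabolic genes Sdha, Fh1 and Gpi1 stood at -0.01 ± 0.20, 0.013 ± 0.15 and -0.55 ± 0.20, and the proteasome genes Psmc6, Psmd6 and Psma7 at 0.005 ± 0.06, 0.028 ± 0.048 and -0.37 ± 0.039. The actin gene Actb was at -0.32 ± 0.01 and Gapdh at -0.30 ± 0.12. Centring on the mode instead of the median raised the median of all promoters to 0.15 for Ezh1 and 0.13 for Ezh2, and these 4 lists stayed below other promoters under that centring.

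Keratins, blood cell markers, germ line genes and olfactory receptors had few promoters past the threshold. Of 40 keratins none passed for Ezh2 in limma's treat (0 over the list alone), with Krt18 at 0.89 ± 0.39, Krt8 at 0.63 ± 0.43 and Krt17 at -0.27 ± 0.026. Krt18 passed with the batch as a block (adjusted p 0.00305) and Krt18 and Krt8 passed without Ezh2 replicate 2 (7.41e-08 and 0.00118). Of 22 lymphoid and myeloid markers 1 passed (1 over the list alone), the lipopolysaccharide receptor gene Cd14 at 1.35 ± 0.23, while Il7r was at 0.21 ± 0.17 and Cd68 at -0.44 ± 0.16. Of 25 spermatogenesis and germ line genes 1 passed (1 over the list alone), Tdrd6 at 1.35 ± 0.24, while Taf7l was at 0.64 ± 0.14 and Tnp2 at -0.13 ± 0.11. These 3 lists had adjusted p of 0.276, 0.217 and 0.163; the keratin and the lymphoid and myeloid lists tested downward while their means were 0.0017 and 0.0026. Of 978 olfactory and vomeronasal receptors 1 passed, Olfr94 at 0.85 ± 0.11, and 0 passed over the list alone. Camera placed that list above other promoters (adjusted p 4.96e-04, lost with an estimated correlation at adjusted p = 0.713), but its mean was -0.028 in replicate 1 and 0.31 in replicate 2. The olfactory call ended with the batch as a block (adjusted p 0.834), and without Ezh2 replicate 2 the list lay 0.17 below other promoters, as it did by 0.18 with normexp background correction; with loess it had an adjusted p of 0.391.

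Over the 21 lists, camera called 11 above and 4 below other promoters for Ezh2, 11 above with the batch as a block, and 0 with an estimated correlation, where 2 lists had an unadjusted p under 0.05. limma's fry, which tests a list against 0 and not against other genes, called 17. The enriched count ranged from 1237 to 1739 when any 1 replicate was left out.

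**Figure D1:**
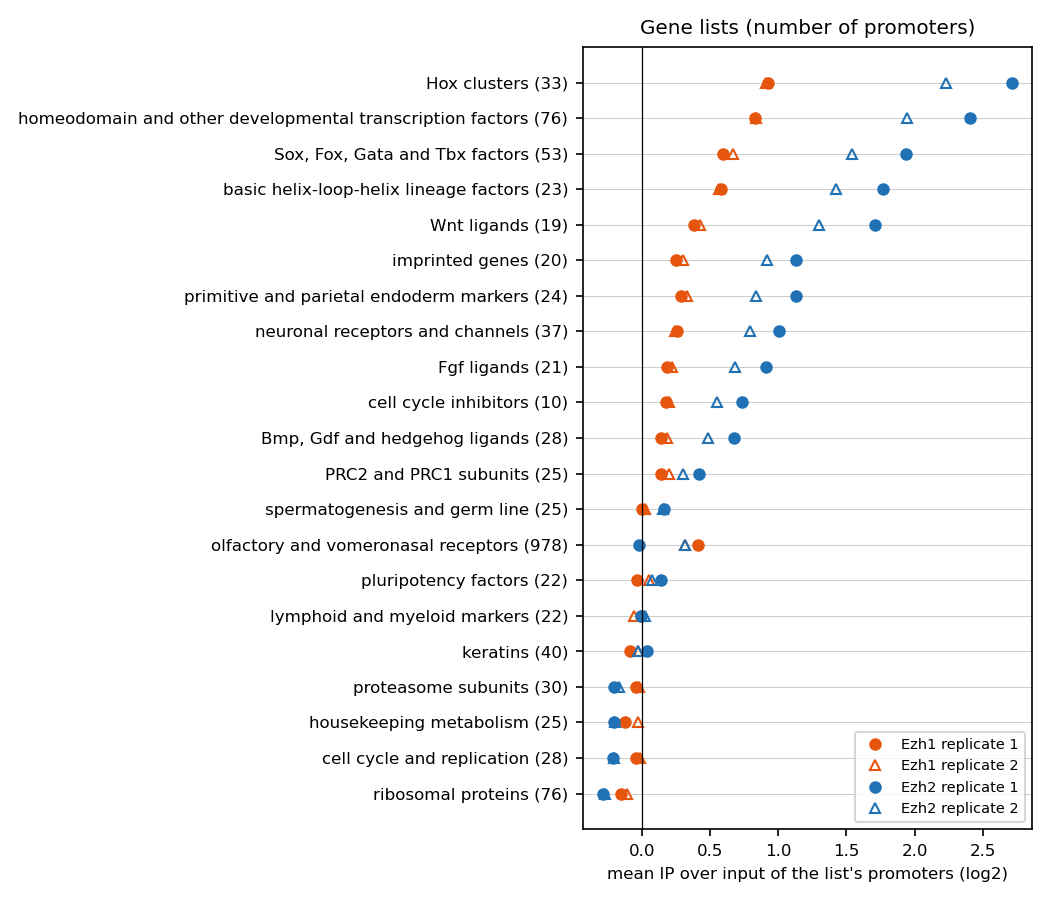
Mean log2 ratio of IP over input for each gene list (horizontal axis), 1 point per replicate, with the number of promoters in parentheses. In Hox clusters both Ezh2 replicates (2.71 and 2.23) lie above both Ezh1 replicates (0.92 and 0.91), whereas ribosomal proteins lie below 0 in all 4.

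The second comparison asked the same of Ezh1. Its highest signals lay at the same kind of gene, but lower. Msx1 was again first at 1.76 ± 0.056 (SD, n = 2), or 3.39 times the array's median ratio. It was followed by Lhx9 at 1.59 ± 0.045, Olig2 at 1.55 ± 0.20, Six3 at 1.55 ± 0.054 and Nkx2-3 at 1.54 ± 0.08. Zic1, a cerebellar zinc finger factor, reached 1.54 ± 0.091, Hoxd10 1.53 ± 0.011, Pax3 1.52 ± 0.042, the limb patterning gene Lmx1b 1.51 ± 0.012 and Pax9 1.51 ± 0.018. Ezh1 was enriched at 89 promoters, or 0.526% of those tested, and at 193 with the batch as a block. All 89 had a ratio above 0.5 in both replicates, which the call itself nearly ensures.

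By list, 10 of 33 Hox promoters passed for Ezh1 (24 over the list alone), such as Hoxa9 at 1.49 ± 0.14 and Hoxb3 at 1.23 ± 0.00051. Homeodomain and other developmental transcription factors had 23 of 76 (48 over the list alone), and the Sox, Fox, Gata and Tbx factors 11 of 53 (25 over the list alone), such as Foxb1 at 1.48 ± 0.04 and Gata6 at 1.44 ± 0.062. Basic helix-loop-helix lineage factors had 3 of 23 (7 over the list alone): Olig2, Neurog2 at 1.38 ± 0.0036 and Hand2 at 1.09 ± 0.056. Endoderm markers had 4 of 24 (6 over the list alone): Gata6, Pdgfra at 1.17 ± 0.045, Foxa2 at 1.01 ± 0.029 and Sox17 at 0.97 ± 0.0025, while Gata4 was at 1.06 ± 0.17 with an adjusted p of 0.131. Imprinted genes had 1 of 20 (2 over the list alone), Grb10 at 1.00 ± 0.049. Wnt ligands and neuronal receptors and channels had 0 promoters that passed, over all genes or over the list alone, with Wnt11 at 0.89 ± 0.07, Wnt7b at 0.85 ± 0.11, Kcna1 at 0.79 ± 0.047 and Grin2c at 0.52 ± 0.084. For these 8 lists in the order given, with Wnt ligands and neuronal genes last, camera's adjusted p was 9.44e-23, 3.59e-32, 1.45e-13, 4.83e-09, 0.0200, 0.00721, 1.70e-05 and 6.18e-05. None held with an estimated correlation, where the adjusted p = 0.588 for endoderm markers and 0.536 for the other 7. With the batch as a block all 8 kept an adjusted p of 7.04e-04 or less, while without Ezh1 replicate 2 endoderm markers had an adjusted p of 0.0525. On design 1 alone endoderm markers had 0.188, and on design 2 alone imprinted genes had 0.191.

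Fgf ligands had 0 of 21 promoters enriched for Ezh1 (1 over the list alone), with Fgf16 at 0.91 ± 0.15 and Fgf9 at 1.01 ± 0.11, and an adjusted p of 0.0762. The Fgf list passed with the batch as a block and without either Ezh2 replicate (adjusted p 0.0277 each), and without Ezh1 replicate 1 (0.0361). The Bmp, Gdf and hedgehog ligands (0 of 28), cell cycle inhibitors (0 of 10; 1 over the list alone) and PRC2 and PRC1 subunits (1 of 25; 3 over the list alone) had adjusted p of 0.195, 0.311 and 0.195. Ihh was at 0.86 ± 0.031, Cdkn2a at 0.81 ± 0.076 and Cbx8 at 1.14 ± 0.027, and the PRC gene that passed was Bmi1 at 1.13 ± 0.13. Pluripotency factors had 1 of 22 (1 over the list alone), Otx2 at 2.15 times the array's median ratio. That list had a camera adjusted p of 0.195, a median of -0.050 and a mean of 0.0031. Pou5f1 was at -0.16 ± 0.066 (0.026 with centring on the mode) and Sox2 at 0.18 ± 0.051. Promoters of Ezh2, Eed and Suz12 were at 0.34 ± 0.12, 0.14 ± 0.035 and 0.19 ± 0.10 for Ezh1 (Suz12 -0.035 with normexp).

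No promoter passed treat for Ezh1, over all genes or the list alone, in ribosomal proteins, housekeeping metabolism, keratins, cell cycle and replication, proteasome subunits, lymphoid and myeloid markers, or spermatogenesis and germ line. Ribosomal proteins (median -0.13), housekeeping metabolism (-0.093) and keratins (-0.063) lay below other promoters, with adjusted p of 5.72e-08, 0.0203 and 0.0117. The batch as a block left 1.41e-06, 0.0223 and 0.0184, and an estimated correlation ended all 3 calls (adjusted p = 0.536 each). The keratin call was also lost with normexp (adjusted p 0.191), centring on the mode (0.340), probes within 1 kb (0.113) and the probe length trend removed (0.0556), and the metabolism call with the highest window (0.0711) and on design 2 alone (0.591). Without Ezh1 replicate 1 the metabolism list had an adjusted p of 0.0639, while lymphoid and myeloid markers passed downward at 0.0179. The other 4 lists had adjusted p of 0.177, 0.111, 0.0762 and 0.575 in the order named; germ line genes tested downward with a median of -0.0030 and a mean of 0.0068. Actb stood at -0.25 ± 0.12 and Gapdh at -0.18 ± 0.13. Of 978 olfactory and vomeronasal receptors 2 passed (0 over the list alone), Olfr487 at 1.21 ± 0.009 over 4 probes and Olfr1034 at 1.21 ± 0.27 over 5 probes (chromosome 2, 85889070 to 85892026), while Vmn2r57 was at -0.45 ± 0.18. Both calls were lost with normexp, with dim probes removed and with the median over probes, and that of Olfr487 also on design 1 alone. Over the alternatives the Ezh1 ratio fell as low as 0.54 at Olfr487 and 0.55 at Olfr1034. The receptor list had a mean of 0.41 in replicate 1 and 0.31 in replicate 2 and lay above other promoters (adjusted p 4.43e-32, and 2.78e-37 with the batch as a block). Its adjusted p = 0.536 with an estimated correlation. Among receptor promoters outside the called groups, Ezh1 signal showed no peak at the start. It was 0.41 and 0.27 in replicates 1 and 2 in the farthest upstream bin and 0.15 and 0.072 in the 500 bases after the start. Ezh2 replicate 2 had 0.31 and 0.084 in these bins. A probe offset was thus not separated from binding for this list.

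Camera thus called 9 lists above and 3 below other promoters for Ezh1, 10 above with the batch as a block, and 0 with an estimated correlation, where 0 lists had an unadjusted p under 0.05. fry called 0 lists for Ezh1, with 6 at an unadjusted p under 0.05. The Ezh1 count rested on both Ezh1 replicates: without either one treat called 0 promoters, with 222 and 292 at an unadjusted p under 0.05 without replicates 1 and 2, and without either Ezh2 replicate it called 268. It was also 0 with normexp background correction (197 unadjusted), 2 with limma's trend and robust options and 423 with quantile normalization.

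The third comparison asked whether Ezh1 and Ezh2 marked the same promoters. Of the 89 promoters enriched for Ezh1, 87 were enriched for Ezh2. Independent lists of these sizes would share 7.62 (Fisher's exact test, one-sided, p = 4.12e-91). The p-value assumes independent promoters, whereas some share probes or overlap, and both call sets came from 1 fit on the same probes. Probe effects shared by the arrays would also raise the overlap, so the p-value does not measure shared binding. Olig2, Pax3, Hoxd10, Gata6 and Foxa2 were among the 87, and the 2 others were Olfr487 and Olfr1034. Both receptors lost the Ezh1 call with normexp, with dim probes removed and with the median over probes. With dim probes removed, all 122 promoters enriched for Ezh1 were also enriched for Ezh2. With the batch as a block 187 promoters were shared. With a treat threshold of 0, which also admits small departures from the array median, 1143 of 2208 promoters enriched for Ezh1 were enriched for Ezh2. The near-complete overlap thus holds for the strongest Ezh1 signals. Without either Ezh1 replicate no promoter was called for Ezh1, so 0 were shared, and without Ezh2 replicates 1 and 2 the overlap was 250 and 249. The overlap was also 0 with normexp and with limma's trend and robust options, which called 0 and 2 promoters for Ezh1. At the 1448 Ezh2-enriched promoters the median log2 ratio was 1.34 for Ezh2 (interquartile range 1.03 to 1.87) and 0.38 for Ezh1 (0.22 to 0.62). Ezh1 was above 0 in both replicates at 1375 of them and above 0.5 in both at 445.

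Across promoters, which are not independent replicates, the mean Ezh1 and Ezh2 profiles had a Pearson r of 0.703 and a Spearman rho of 0.648, and an r of 0.909 over Ezh2-enriched promoters. Replicates of Ezh1 correlated at r = 0.831 and those of Ezh2 at 0.928. Within scan batches, Ezh1 against Ezh2 gave r = 0.514 in replicate 1 and 0.820 in replicate 2, and across batches 0.711 and 0.667. The 1448 highest promoters of Ezh1 replicate 1 and of Ezh2 replicate 2 shared 607, and those of Ezh1 replicate 2 and Ezh2 replicate 1 shared 739 (odds ratios of 12.5 and 21.7). Probe by probe, nearly all probes at Msx1, Hoxd10 and Gata6 lay above 0 in every replicate of both antibodies, and most probes at Pou5f1 and Actb lay below 0.

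**Figure D2:**
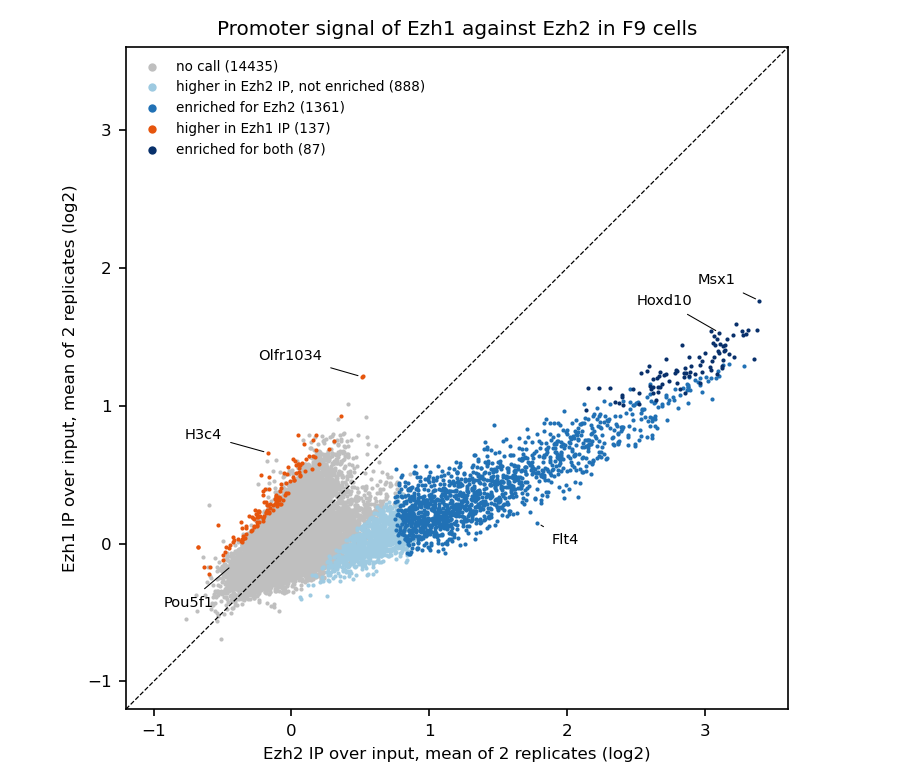
Mean log2 ratio over input of Ezh1 (vertical) against Ezh2 (horizontal) for 16908 promoters, with called promoters in colour and the line of equal values dashed. Promoters enriched for both (87) lie at the right end, below the line of equal values.

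**Figure D3:**
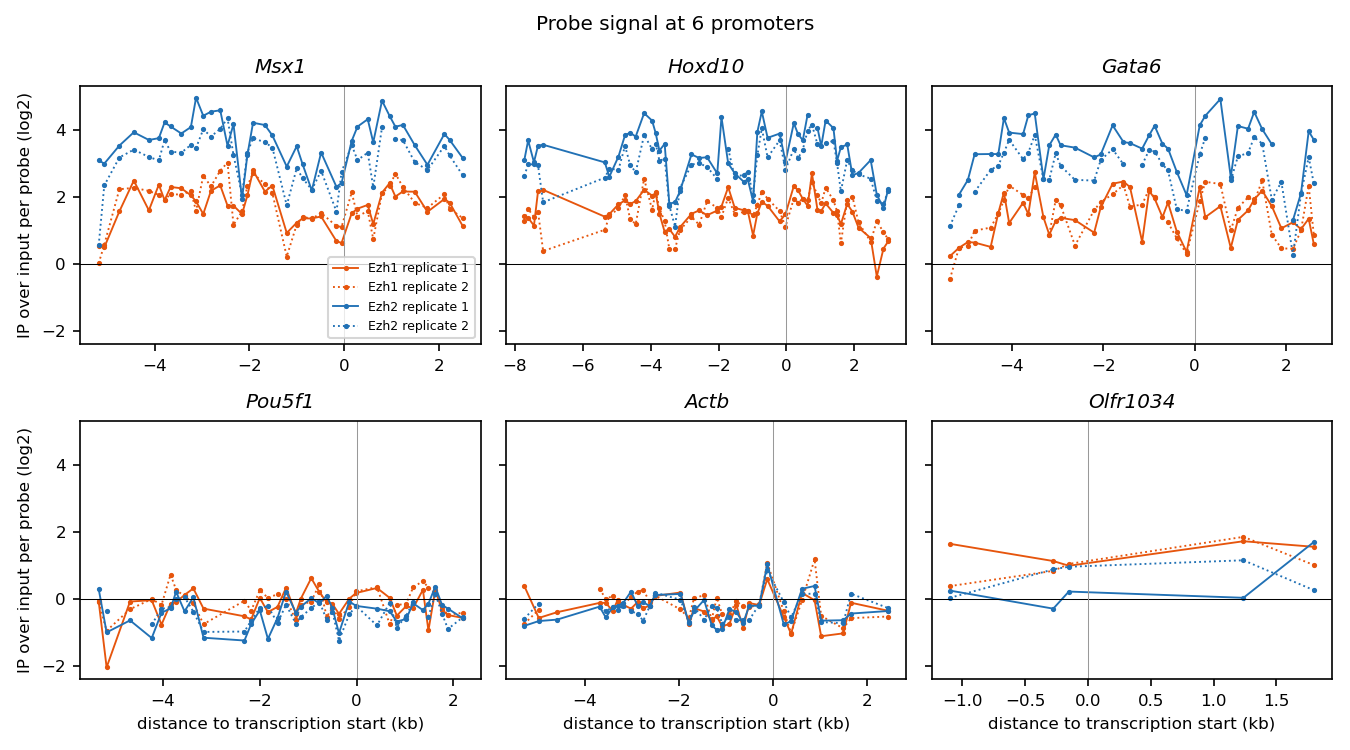
Log2 ratio of IP over input of single probes (vertical) against distance to the transcription start in kb (horizontal) at 6 promoters, with a line per replicate. The mean of Ezh2 lies above that of Ezh1 at nearly all probes of Msx1, Hoxd10 and Gata6, and Olfr1034 has only 5 probes.

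The last comparison asked where the IPs differed. With the main scaling, Ezh2 exceeded Ezh1 most at the Hox-cluster microRNAs mmu-mir-196b, by 2.02 ± 0.20 (SE), and mmu-mir-196a-2, by 2.00 ± 0.26 over 9 probes. Also among the largest were the unnamed transcript D930049A15Rik at 1.89 ± 0.23, Hoxb6 at 1.88 ± 0.19 and Gata2 at 1.87 ± 0.21. The liver and neuronal factor gene Onecut3, Hoxb3 and Six3os1 differed by 1.86 ± 0.19, 1.85 ± 0.17 and 1.85 ± 0.17. With 99th percentile scaling these differences were smaller and the order changed: mmu-mir-196b had 0.72, mmu-mir-196a-2 0.90, D930049A15Rik 0.72 (its call lost, adjusted p 0.0575), Hoxb6 0.74, Gata2 0.62, Onecut3 0.83, Hoxb3 0.70 and Six3os1 0.63, against 0.92 for Dppa3 and 0.91 for Cdkn1c. Ezh2 was higher at 2323 promoters (2352 with the batch as a block), including 1435 of the 1448 Ezh2-enriched ones and all 87 enriched for both. All 2323 had the same sign in both batches, which the call itself nearly ensures. Over Ezh2-enriched promoters the median difference was 1.01, with 1.21 in batch 1 and 0.83 in batch 2.

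Every Hox promoter was higher in the Ezh2 IP (33 of 33; 33 over the list alone), such as Hoxa9 at 1.67 ± 0.20 and Hoxd10 at 1.57 ± 0.14. So were 74 of 76 homeodomain and other developmental factors (75 over the list alone), such as Msx1 at 1.63 ± 0.17 and Six3 at 1.83 ± 0.22, with Pax4 at 0.33 ± 0.12 and an adjusted p of 0.101 (0.00926 without Ezh2 replicate 2). So were 40 of 53 Sox, Fox, Gata and Tbx factors (45 over the list alone), such as Gata6 at 1.71 ± 0.21 and Foxb1 at 1.61 ± 0.18, and 18 of 23 basic helix-loop-helix factors (18 over the list alone), such as Olig2 at 1.76 ± 0.21. Median differences of these 4 lists were 1.68, 1.42, 1.36 and 1.24, with 1.90, 1.68, 1.52 and 1.47 in batch 1 and 1.43, 1.17, 1.12 and 1.04 in batch 2. Camera's adjusted p was 6.26e-32, 4.08e-48, 1.35e-26 and 1.41e-12, and the 4 calls were lost with an estimated correlation (adjusted p = 0.305 each). With 99th percentile scaling these differences shrank, and the call was lost at Msx1 (0.15, adjusted p 0.417), Hoxd10 (0.26, 0.157), Hoxa9 (0.36, 0.0575), Foxb1 (0.35, 0.0827) and Olig2 (0.42, 0.135), and with quantile normalization at Msx1 (0.27, 0.104) and Hoxd10 (0.31, 0.0723).

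Wnt ligands were higher in the Ezh2 IP at 17 of 19 promoters (17 over the list alone), such as Wnt11 at 1.73 ± 0.17; neuronal receptors and channels at 26 of 37 (31 over the list alone), such as Kcna1 at 1.57 ± 0.18; and imprinted genes at 13 of 20 (14 over the list alone), such as Igf2 at 1.48 ± 0.14. Endoderm markers were higher at 14 of 24 (14 over the list alone), such as Pdgfra at 1.63 ± 0.16, Gata4 at 1.70 ± 0.19 and Sox17 at 1.17 ± 0.11. Fgf ligands were higher at 12 of 21 (14 over the list alone), such as Fgf16 at 1.70 ± 0.20, Bmp, Gdf and hedgehog ligands at 12 of 28 (13 over the list alone), such as Ihh at 1.31 ± 0.15, and cell cycle inhibitors at 4 of 10 (5 over the list alone), namely Cdkn1c at 1.76 ± 0.17, Cdkn2a at 1.24 ± 0.12, Cdkn2c at 0.73 ± 0.11 and Cdkn1a at 0.75 ± 0.13. Median differences of these 7 lists were 1.20, 0.60, 0.64, 0.76, 0.47, 0.23 and 0.19. Within batch 1 they were 1.48, 0.62, 0.73, 1.00, 0.53, 0.41 and 0.32, and within batch 2 0.86, 0.49, 0.61, 0.46, 0.43, 0.050 and 0.15. Camera's adjusted p was 1.68e-14, 5.43e-15, 1.75e-08, 4.99e-07, 9.47e-08, 2.29e-04 and 0.0165. With an estimated correlation the adjusted p = 0.305, 0.305, 0.305, 0.330, 0.337, 0.437 and 0.459. With the batch as a block adjusted p was at most 0.00397 for these 7 lists and the 4 transcription factor lists. The inhibitor list no longer passed with 99th percentile scaling (adjusted p 0.0566), nor did Sox17 (0.30, adjusted p 0.126). Under that scaling the median difference of all 2323 promoters higher in the Ezh2 IP fell from 0.78 to 0.49. The sizes given here thus hold for the main scaling.

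In the lists that camera left uncalled for the difference, 5 of 25 PRC genes were higher in the Ezh2 IP (5 over the list alone, with 2 lower), among them Cbx8 at 1.74 ± 0.20, Bmi1 at 1.49 ± 0.14, Cbx2 at 0.82 ± 0.11 and Pcgf1 at 0.60 ± 0.12. Pluripotency factors had 3 higher in the Ezh2 IP, Otx2 at 1.55 ± 0.14, Dppa3 at 1.30 ± 0.14 and Dnmt3b at 0.71 ± 0.14, and 1 higher in the Ezh1 IP, Zfp42 at -0.37 ± 0.10 (4 and 1 over the list alone). Keratins had 2 of 40 higher in the Ezh2 IP (1 over the list alone), Krt18 at 0.87 ± 0.17 and Krt8 at 0.74 ± 0.18, whose adjusted p became 0.0838 and 0.201 without Ezh1 replicate 1 and 0.0779 and 0.128 without Ezh1 replicate 2, and 0.0637 and 0.145 with normexp. Germ line genes had 2 of 25 (2 over the list alone), Tdrd6 at 1.07 ± 0.13 and Tex11 at 0.46 ± 0.11, and lymphoid and myeloid markers 1 of 22 (1 over the list alone), Cd14 at 0.97 ± 0.14. Adjusted p of these 5 lists was 0.959, 0.854, 0.750, 0.0866 and 0.997. The PRC list had a median difference of -0.062 and a mean of 0.19, and the pluripotency list -0.064 and 0.098. The differences of keratins and of lymphoid and myeloid markers from other promoters turned from -0.0095 to 0.061 and from -0.035 to 0.034 with 99th percentile scaling. Differences at Ezh2, Eed, Suz12, Pou5f1 and Sox2 were -0.22 ± 0.12, -0.13 ± 0.10, -0.23 ± 0.11, -0.27 ± 0.11 and -0.27 ± 0.11, none past the threshold, with adjusted p from 0.143 to 0.49; Ezh2 and Sox2 passed with quantile normalization (0.0472 and 0.0368) and Pou5f1 with the probe length trend removed (0.0403).

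In the main fit 137 promoters were higher in the Ezh1 IP (221 with the batch as a block). All 137 had the same sign in both batches, which again the call nearly ensures. That count was 17 with centring on the mode, 367 with MAD scaling, 654 with loess, 691 with 99th percentile scaling, 821 with limma's trend and robust options and 1407 with quantile normalization. The largest differences lay at histone, receptor and other genes, several of them tiled by few probes. They included the histone H3 gene H3c4 at -0.83 ± 0.11 over 4 probes (chromosome 13, 22941137 to 22941708), the transporter gene Slco6c1 at -0.74 ± 0.17 over 3, the natural killer receptor gene Klra6 at -0.72 ± 0.19, Olfr1034 at -0.70 ± 0.15, Olfr487 at -0.70 ± 0.18, Olfr761 at -0.67 ± 0.13 and the vomeronasal receptor Vmn1r33 at -0.65 ± 0.16 over 16. The histone genes H2bc3 and H3c3, which share their 6 probes, were at -0.65 ± 0.14, and the condensin gene Smc4 at -0.63 ± 0.11 over 15 probes. With normexp background correction the difference turned to 0.14 at H3c4 and 0.16 at Olfr761, and the call was lost at Slco6c1 (adjusted p 0.103), Olfr1034 (0.0914), Olfr487 (0.0693), H2bc3 and H3c3 (0.983) and Smc4 (0.0949). With the median over probes it was lost at Slco6c1 (0.0726), Klra6 (0.104), Olfr1034 (0.0840), Olfr487 (0.0727), Olfr761 (0.162), Vmn1r33 (0.160) and Smc4 (0.0864). Without Ezh1 replicate 1 the call was lost at Klra6 (adjusted p 0.174), Olfr1034 (0.184), Olfr487 (0.231), Olfr761 (0.113), Vmn1r33 (0.253), H2bc3 and H3c3 (0.123) and Smc4 (0.0725). Without Ezh1 replicate 2 it was lost at Slco6c1 (0.186), Klra6 (0.199), Olfr487 (0.174), Vmn1r33 (0.124), H2bc3 and H3c3 (0.116) and Smc4 (0.0631), and without Ezh2 replicate 1 at Olfr487 (0.0578). The median Ezh1 ratio of the 137 was 0.29 and the median Ezh2 ratio -0.16, 31 had an Ezh1 ratio above 0.5, and 2, Olfr1034 and Olfr487, were enriched for Ezh1.

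Olfactory and vomeronasal receptors made up 27 of the 137, and 2 receptor promoters were higher in the Ezh2 IP, Olfr94 at 0.53 ± 0.11 and Olfr463 at 0.39 ± 0.11 (0 and 0 over the list alone). The receptor list lay below other promoters in Ezh2 minus Ezh1 (adjusted p 5.43e-15, 1.46e-14 with the batch as a block, and adjusted p = 0.491 with an estimated correlation). Its median difference of -0.22 split into -0.46 in batch 1 and 0.017 in batch 2, so it did not hold within batch 2. Cell cycle and replication, ribosomal proteins, housekeeping metabolism and proteasome subunits also lay below other promoters, with median differences of -0.17, -0.15, -0.12 and -0.15 and adjusted p of 1.28e-04, 1.93e-06, 0.0109 and 2.86e-04. With an estimated correlation the adjusted p = 0.305, 0.305, 0.437 and 0.305, and with the batch as a block 0.00265, 2.36e-04, 0.0271 and 0.00637. Within batches 1 and 2 the medians were -0.18 and -0.17, -0.15 and -0.16, 0.026 and -0.19, and -0.15 and -0.15, so that of housekeeping metabolism differed in sign. The metabolism list lost its call without Ezh1 replicate 2 (adjusted p 0.125) without Ezh2 replicate 2 (0.0610) and on design 1 alone (0.120), and it and the ribosomal list lost theirs with 99th percentile scaling (0.254 and 0.139). In these 4 lists 2 promoters were higher in the Ezh1 IP and 0 over the list alone, among them the ribosomal gene Rps25 at -0.44 ± 0.12. Actb and Gapdh differed by -0.074 ± 0.11 and -0.12 ± 0.12, and with 99th percentile scaling by 0.093 and 0.011; Actb differed by 0.047 with normexp.

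**Figure D4:**
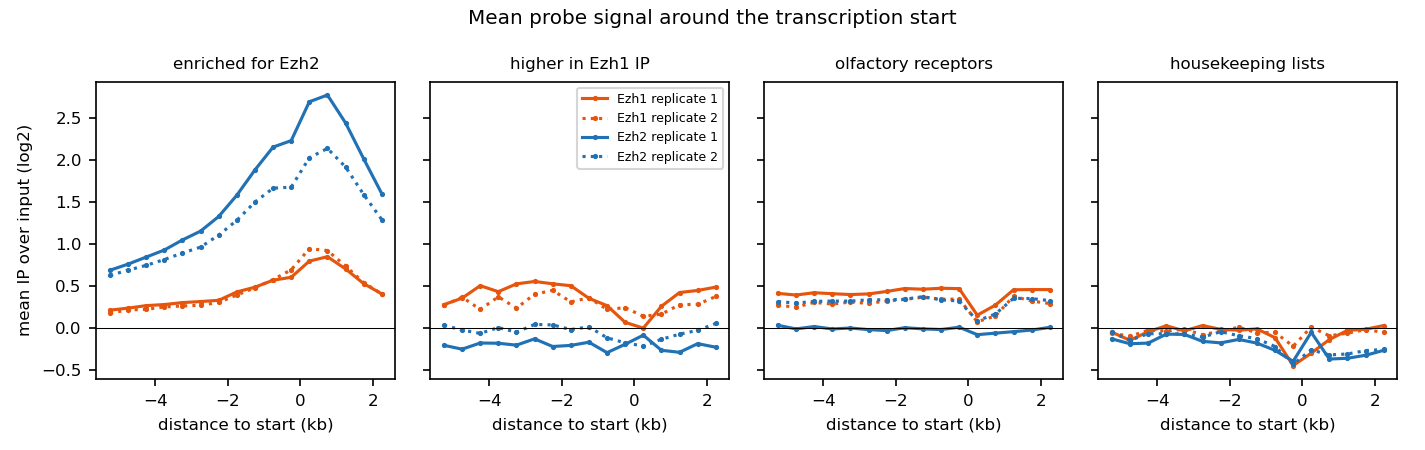
Mean log2 ratio of IP over input (vertical) in bins of 500 bases against distance to the transcription start in kb (horizontal) for 4 groups of promoters, with a line per replicate. At Ezh2-enriched promoters, chosen by their Ezh2 signal, the highest bins are 2.77 and 2.13 for Ezh2 and 0.85 and 0.94 for Ezh1, all within 1 kb downstream of the start, and promoters higher in the Ezh1 IP show no such rise.

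Over the 21 lists 16 differed, 11 upward and 5 downward, as they did with the batch as a block, and 0 with an estimated correlation, where 0 lists had an unadjusted p under 0.05. fry called 0 lists, with 14 at an unadjusted p under 0.05. The number of promoters higher in the Ezh1 IP was 3 and 19 without Ezh1 replicates 1 and 2 and 1630 without Ezh2 replicate 2, and the number higher in the Ezh2 IP was 1102 without Ezh1 replicate 1, 1246 without Ezh1 replicate 2 and 3106 without Ezh2 replicate 2. The share of called differences that were higher in the Ezh2 IP was 94.4%. It was 82.3% with loess (3039 higher in the Ezh2 IP and 654 in the Ezh1 IP), 60.5% with quantile normalization (2158 and 1407), 71.9% with 99th percentile scaling (1765 and 691), 76.2% with trend and robust (2625 and 821) and 65.6% without Ezh2 replicate 2 (3106 and 1630).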

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

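Each of 10 quality values was compared over the 4 arrays of each antibody by a test for a sample far from the others, in 20 tests. The test's nominal rate of about 1 in 20 groups would give about 1 flag, and 4 were found. That rate assumes 4 arrays that vary alike, whereas they came from Agilent and GenePix scans. Several of the quality values are also related, so the expected number is only a rough guide. On array design 2, Ezh1 replicate 1 had input well above background at 87.9% of probes, where the other 3 Ezh1 arrays had 98.0% to 99.5%. The same array had IP signal well above background at 91.8% of probes (other Ezh1 arrays 99.4% to 99.8%) and a surrogate signal at 14.7% (other Ezh1 arrays 0.559% to 2.22%), so 3 of the 4 describe 1 dim array. The remaining array was Ezh2 replicate 2 on design 2, where 4.78% of probes carried an outlier mark from the scanner software (other Ezh2 arrays 0.0662% to 0.339%).

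Of the tests below, those on 1 scale factor and on probe length were written before their results were seen, and those on the dim array, the scan batches and the start of transcription after. The wording of the scale explanation was narrowed to 1 log2 factor after the counts under scaling had been seen, the verdict rule of the matched lists was tightened after their value was seen, and the spread for the start was added later. All samples are undifferentiated F9 cells, so the design gives no other biological group to weigh, and the only biological explanation weighed here is Ezh1 binding at the transcription start.

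More promoters were higher in the Ezh2 IP (2323) than in the Ezh1 IP (137), though with 99th percentile scaling 1765 stood against 691. If 1 log2 scale factor between arrays were the cause, scaling each array to one 99th percentile should have ended most calls, but 72.9% of the promoters higher in the Ezh2 IP kept theirs, with a median difference of 0.49 (interquartile range 0.38 to 0.61) after scaling against 0.78 before. That argues against such a factor as the whole cause, but not as part of it: at the 87 promoters enriched for both, the median difference fell from 1.61 to 0.43 and 57 kept the call. The dim array is not the whole cause either. Design 1, which does not include that array, alone gave 1137 promoters higher in the Ezh2 IP against 61 in the Ezh1 IP. At the 742 promoters of design 1 that the main fit called enriched for Ezh2, the median difference was 0.999, against 1.02 on design 2. Those promoters were chosen by their Ezh2 signal, which favours a positive difference, so their median says less. A lower specific yield of the Ezh1 IP, such as from a weaker antibody, stays open, because no mock IP or spike-in was used here.

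Olfactory and vomeronasal receptor promoters were lower in Ezh2 minus Ezh1, with a median of -0.218 over 978 promoters. Random lists matched on mean probe length, a proxy for base composition, had a median of -0.198 and ranged from -0.215 to -0.174 (SD 0.00608). The receptors thus lay just below the lowest of these lists, but by under 1 SD from that lowest list. Other promoters with like probe length were nearly as low, so most of the difference is not particular to receptors. The data cannot tell whether base composition is the cause. Their median was 0.017 in batch 2 and -0.46 in batch 1; these batch medians prompted the comparison of batches, so it decides nothing about a batch as the cause. Whether any of this difference is binding stays open.

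Promoters higher in the Ezh1 IP numbered 137. A probe length trend is argued against as their whole cause, since 99.3% of them kept the call with that trend removed. The same step raised the count to 414, so a kept call is weak evidence. Probe length is only a proxy and no GC content was computed, so base composition itself was not settled. Their Ezh1 signal near the start minus that of the flanks was -0.215 in replicate 1 and -0.060 in replicate 2 (112 promoters, bootstrap SE 0.0533). That argues against an Ezh1 rise at the start as large as at Ezh2-enriched promoters (0.47 and 0.57). In replicate 1 promoters outside the plotted groups also dipped, to -0.13 in the 500 bases before the start against 0.041 in the farthest upstream bin. In replicate 2 they did not (0.0024 and 0.0045). A smaller rise on top of such a dip was not excluded. Many of these calls depend on the processing. Of the 137, normexp kept 17, the median over probes 54 and probes within 1 kb 11, while MAD scaling and quantile normalization kept all 137. What raises these promoters stays open.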

How the results depend on the processing

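Counts are given in the order enriched for Ezh2, enriched for Ezh1, enriched for both, higher in the Ezh2 IP and higher in the Ezh1 IP, which were 1448, 89, 87, 2323 and 137 in the text. They became 1247, 0, 0, 2137 and 140 with normexp (only 17 of the 140 among the 137), 1607, 228, 225, 3039 and 654 with loess, 1658, 164, 161, 1980 and 17 with centring on the mode, and 1510, 185, 183, 2569 and 367 with MAD scaling. Quantile normalization gave 1237, 423, 375, 2158 and 1407. Probes within 1 kb of the start gave 2165, 338, 334, 2647 and 57 (11 of them among the 137), the highest window of 5 probes 2795, 756, 677 and 2807 for the first 4, with the last count near 137 but only 21 promoters shared with the 137, and limma's trend and robust options 1320, 2, 0, 2625 and 821. Array designs 1 and 2 alone, with fewer promoters tested, gave 729, 45, 44, 1137 and 61 and 721, 51, 51, 1200 and 79. A treat threshold of 0 gave 3493, 2208 and 1143 for the first 3, and a threshold of 1 gave 692, 0 (60 at an unadjusted p under 0.05) and 0. A threshold of 0.5 on the difference gave 691 and 0 (1 unadjusted) for the last 2. Added after seeing the data, 99th percentile scaling gave 1111, 435, 387, 1765 and 691 and removal of the probe length trend 1525, 133, 131, 2748 and 414. Except where a step itself changes the promoters, samples or threshold tested, the cause was not tested. The other settings kept these 5 counts within 1.5 times, though with the median over probes 54 of 97 promoters higher in the Ezh1 IP were among the 137. The numbers of lists called stayed within 1.5 times except with an estimated correlation, where they were 0, 0 and 0. That setting had little power, with 2 residual degrees of freedom.

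Leaving out 1 replicate gave 1237 to 1739, 0 to 268, 0 to 250, 1102 to 3106 and 3 to 1630 for the same counts, r from 0.607 to 0.793, and 11 to 12, 8 to 10 and 15 to 16 lists called upward for Ezh2, upward for Ezh1 and for the difference; the lone sample is then assumed to vary like the other group. The replicate number as a block gave 1481, 193, 187, 2352 and 221. Deviations of same-numbered samples from their group means correlated at -0.298, so the crossed pairing was added, and it gave 1538, 110, 105, 2756 and 611. Reversed values were the differences of H3c4 (0.14) and Olfr761 (0.16) with normexp, and the Ezh2 shift of olfactory and vomeronasal receptors with normexp (-0.18), probes within 1 kb (-0.14), the highest window (-0.18) and without Ezh2 replicate 2 (-0.17, against 0.19 without Ezh2 replicate 1). Of 6670 comparisons of named genes with an alternative 6152 were unchanged, 204 lost a call, 312 gained one and 2 reversed. Of 1506 for lists 1409 were unchanged, 62 lost a call, 31 gained one and 4 reversed. Results called in neither fit counted as unchanged, so these totals do not give the share of calls that were kept. With normexp, which left no Ezh1 call, 24 of 95 Ezh1 values of named genes lost a call and 71 counted as unchanged. A correction for GC content was not run. Signal over background, 2.58 to 3.22 for input on the Agilent scans, limits replicate 1 of both antibodies, and the Ezh1 calls rest on 2 replicates.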

Other observations

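Groups outside the fixed lists were chosen after the values were seen, so their counts are given without a test, beside 8.56% of all promoters enriched for Ezh2. Protocadherins, cell adhesion genes that give neurons distinct surfaces, had 37 of 62 promoters enriched for Ezh2, such as Pcdh8 at 2.63 ± 0.39 and Pcdh7 at 3.13 ± 0.52. Semaphorins, ephrins and Eph receptors, which guide axons, had 12 of 36, such as Sema6a at 2.22 ± 0.34. Frizzled receptors and secreted Wnt inhibitors had 8 of 17, such as Fzd8 at 2.47 ± 0.40 and the head inducer Dkk1 at 1.27 ± 0.092. Class I histocompatibility genes of the Q, T and M regions had 4 of 13, among them H2-Q10 at 1.97 ± 0.46. Zinc finger genes named Zfp had 8 of 283, Zfp503 at 3.01 ± 0.54 being one of the 8. MicroRNA genes had 22 of 219.

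Histone cluster genes had 2 of 52 promoters enriched for Ezh2 and gave 5 of the 137 promoters higher in the Ezh1 IP. These were H2bc3 and H3c3, which share their probes and had an adjusted p of 0.983 with normexp, H3c4, which turned to 0.14 with normexp, H3c15 at -0.45 ± 0.12 and H3c8 at -0.46 ± 0.11. Of 350 tiled regions without a gene name in the files, with 7844 probes, 20 were enriched for Ezh2, 1 for Ezh1 and 34 were higher in the Ezh2 IP. One on chromosome 2, 118636830 to 118644679, had 2.48 for Ezh2 and 0.80 for Ezh1, and one on chromosome 1, 155701561 to 155709428, had 2.22 and 1.08.

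A hypothesis written before its test was that single promoters depart from the common relation of Ezh1 to Ezh2 in a repeatable way. Over the 1448 Ezh2-enriched promoters the residuals of replicate 1 and replicate 2 correlated at 0.487 (0.406 with the pairing of antibodies exchanged), which is consistent with repeatable departures, though probe effects shared by the arrays would give the same. The largest departures toward more Ezh1 were at Fzd3 (0.37), Pknox2 (0.36) and Nkx2-4 (0.36), and toward less at Flt4 (-0.53), Nol3 (-0.33) and Myo3a (-0.32), with only 3 probes at Flt4 and an Ezh1 SD of 0.35 at Fzd3, about as large as its departure. Mean probe length was 58.8 bases for olfactory and vomeronasal receptors, 57.3 for promoters higher in the Ezh1 IP, 53.1 for Ezh2-enriched promoters and 54.5 for all promoters.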
